A study of Mus musculus with 16 samples.

How the data were processed

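The series holds 16 arrays of placental RNA from CD-1 mice, 4 each from WT dams given PBS, KO (Nrf2-/-) dams given PBS, WT dams given LPS and KO dams given LPS. Placentas were taken at embryonic day 17 and 7 h after the injection. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, placentas were frozen in liquid nitrogen, RNA was extracted with a column kit, its integrity was checked on a Bioanalyzer, and it was labelled with biotin for whole-transcript Affymetrix arrays. Per the design text each array represents several placentas of a single litter. The p-values measure the spread between arrays, which is that between litters if the text holds for each array.

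The authors deposited 1 table of log2 expression values with 25206 rows and 16 columns. Per the submitters' processing notes the values were made with RMA (which corrects background, equalizes the distributions of the arrays by quantiles and summarizes probes per probe set) in the affy package, version 1.36.1, under R 2.15.1; the order of steps, any filter and the probe set definition are not given in the sources used here. The log2 scale of the deposited values was read from their range, from 0.189 to 12.1, and from the named method. Array medians lay between 3.78 and 3.86. Because RMA forces the arrays to nearly the same distribution, a change shared by most genes would not be visible. The table gives no detection calls, so the background level is unknown and low values have no bound; the number of arrays limits the precision.

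Row identifiers are gene numbers, and the annotation table of the platform pairs them with symbols. Of 25206 rows, 23185 had 1 gene symbol, 0 had several and 2021 are unnamed here. All 23185 matched a gene of the RefSeq table for mouse by number, and 0 symbols changed. No gene had more than 1 row, so averaging several probe sets per gene, listed among the settings to try, changes nothing and was not run. The files name no genome build, so no coordinates are printed, and positions from the RefSeq table (assembly GRCm38.p6) were used only to tell which genes neighbour each other. No reference genome was used.

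All 16 arrays entered 1 model of 4 group means, fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3 (12 residual degrees of freedom and 3.93 prior degrees of freedom per gene). The 5 comparisons were LPS against PBS in WT, LPS against PBS in KO, KO against WT under PBS, KO against WT under LPS, and the interaction, which is the LPS effect in KO minus that in WT. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 23185 named genes of each comparison, and the threshold was an adjusted p of 0.05. No replicate block was used, because nothing in the labels says that equal replicate numbers share a litter, day or batch. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

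Before the data were examined, 39 gene lists were fixed, covering inflammation, stress, metabolism, trophoblast types and the other cell types that a placenta sample can hold. Members without a named row were left out. Lists were tested with camera on the same model with a preset correlation between genes of 0.01, adjusted over the 39 lists of a comparison. Camera with an estimated correlation, fry and camera with a replicate block were the other settings. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Counts of members past the threshold are given over all genes and adjusted over the list alone. A list mean per array is the mean over members of the log2 value minus that gene's mean over the 16 arrays. Genes around Nfe2l2 and shared calls were tested with two-sided Fisher exact tests. These take genes as independent units, so their p-values do not measure the spread between arrays.

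The genes named were chosen by a rule also fixed beforehand. In each comparison it takes Nfe2l2, the 10 largest rises and 10 largest falls among genes that passed and whose 4 values in one group all lay beyond the 4 of the other (no such condition for the interaction), and up to 4 members with the smallest adjusted p of each list that camera called or that had 3 or more members past the threshold. Where fewer than 5 genes passed, it adds the 5 genes with the smallest p. Predicted genes, Riken clones, receptor families with many copies and small RNAs were passed over in the ranking. Genes named outside the rule are marked as named after their values were seen.

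The other settings fixed beforehand were a fit to only the 8 arrays compared, quantile normalization again, equal array medians, leaving out the 30% of genes with the lowest mean, a variance trend with a robust prior, array weights, the replicate block and leaving out each array in turn. Those added after seeing the data were a covariate of the mean of the Y-linked genes Uty, Kdm5d and Eif2s3y, all 25206 rows, and list tests without WT PBS replicate 3 or without WT LPS replicate 3.

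The gene and list tests were tested on simulated data drawn from the real means and SDs of the 23185 genes with 200 genes changed. For LPS against PBS in WT, 91% of genes changed 2-fold and 56.7% of those changed 1.5-fold were recovered; for the interaction these shares were 74.6% and 25.4%. A simulated list with a shift was called in each of the 5 comparisons, and 0 of 38 unshifted lists were called in any of them. The simulated genes varied independently of one another, so this does not show how often camera calls unshifted lists of correlated genes. No pair of arrays held identical values: correlations between arrays of 1 group ran from 0.9845 to 0.9932.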

Results

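Gene expression was measured on 16 arrays of mouse placenta, taken at embryonic day 17 and 7 h after an injection into the uterus of lipopolysaccharide (LPS, a cell wall component of Gram-negative bacteria that sets off inflammation) or of phosphate-buffered saline (PBS, the vehicle). The dams were wild type (WT) or lacked Nrf2 (KO), both on the outbred CD-1 background. Nrf2 is the product of Nfe2l2 and a transcription factor that drives antioxidant and detoxification genes. Each of the 4 groups (WT PBS, KO PBS, WT LPS and KO LPS) had 4 arrays, and per the design text each array held several placentas of 1 litter. The array was the replicate. Values are log2 expression values, differences are log2 fold changes ± standard error (SE) from limma with 4 arrays per group, and p-values are adjusted by the Benjamini-Hochberg method over 23185 genes unless stated otherwise. Y-linked genes read 1.47 to 2.50 in 7 arrays with little Y-linked signal, a level chosen after the values were seen. Where the lower group of a named gene held an array at or under 2.50, its signal there was not shown to lie above background, so its direction and adjusted p are given and no size of the difference. The number of arrays limits the precision: the median SE of a difference between 2 groups was 0.123 log2 units.

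Nfe2l2 itself was lower in the KO arrays under both treatments. Its mean was 7.40 ± 0.03 (SD, n = 4) in WT PBS, 7.38 ± 0.14 in WT LPS, 6.46 ± 0.15 in KO PBS and 6.32 ± 0.05 in KO LPS, and every KO array lay below every WT array. The difference between KO and WT was -0.94 ± 0.09 under PBS (adjusted p = 5.6e-05) and -1.06 ± 0.09 under LPS (adjusted p = 2e-05). LPS moved Nfe2l2 by -0.02 ± 0.09 in WT (adjusted p = 0.95) and by -0.14 ± 0.09 in KO (adjusted p = 0.39). The position of the probes relative to the deleted part of the gene is not given in the sources used here, so the residual signal does not measure remaining protein.

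On principal components of all named genes, the first component held 26.1% of the variance and the second 15.7%. The KO LPS arrays had first-component scores of 21.7 to 37.5 and the WT arrays of both treatments had negative scores. WT PBS replicate 3 (-38.7) and WT LPS replicate 3 (-29.8) lay farthest from the KO LPS arrays.

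**Figure D1:**
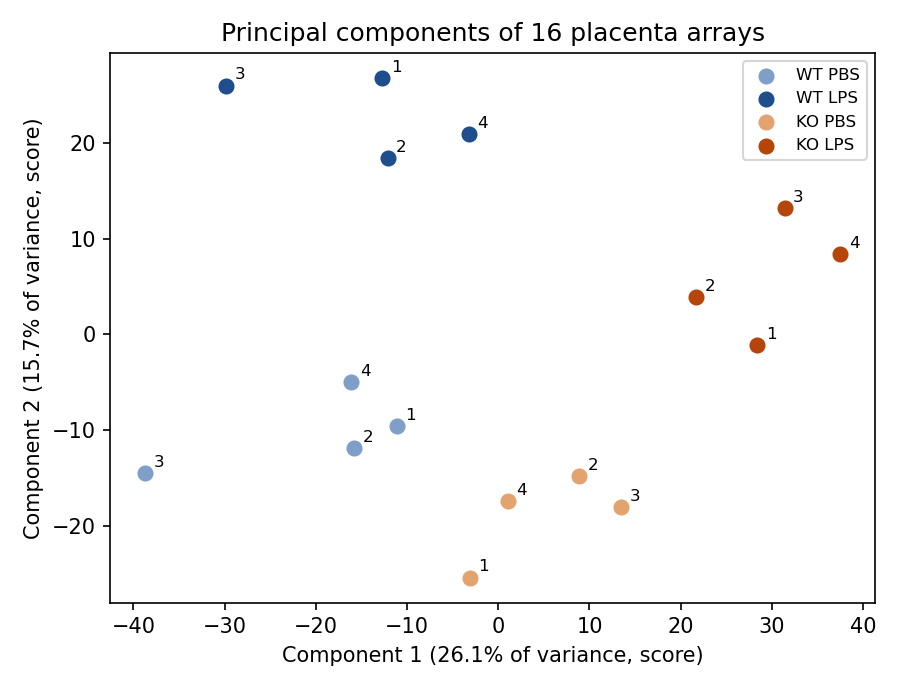
Scores of the 16 arrays on principal components 1 (26.1% of variance) and 2 (15.7%), with colour for group and the replicate number beside each point. The 4 KO LPS arrays lie to the right, the WT LPS arrays lie highest on component 2 (18.4 to 26.8), and WT PBS replicate 3 lies farthest left.

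The response of the WT placenta to LPS was led by chemokines and other inflammatory genes. Acod1, which makes the macrophage metabolite itaconate, rose (adjusted p = 0.00073), from array values of 2.05 to 2.93 under PBS to a mean of 6.11 after LPS. The neutrophil attractants Cxcl1 (3.16 ± 0.34, adjusted p = 0.00019) and Cxcl2 (adjusted p = 0.002) rose, as did the T cell attractants Cxcl11 (adjusted p = 0.008) and Cxcl10 (3.05), Ccl5 (2.69), Ccl3 (2.64), the leukocyte adhesion molecule Madcam1 (3.10), the acute-phase protein Saa3 (2.26) and the interferon-inducible GTPase Gbp5 (2.24). Among the genes that fell furthest were the retinol and alcohol dehydrogenase Adh1 (-1.65 ± 0.36, adjusted p = 0.026), the smooth muscle genes Actg2 (2.84-fold lower) and Cnn1 (-1.44), Pgc (-1.41), Meox2 (adjusted p = 0.025), Mal (-1.32), Btg1c (-1.21), Pcbd1 (-1.21), Tdo2 (-1.14) and Tgfbi (-1.14). In total 501 of 23185 genes passed an adjusted p of 0.05, 311 higher and 190 lower, and 99 of them changed at least 2-fold. The 4 values of each group were fully separated for 9.03% of the genes, where chance gives 2.86%.

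By gene list, 17 of 33 measured interferon-stimulated genes rose in WT placenta and none fell (28 rose when adjusted over the list alone), with a median of 0.91. Gbp3 (2.03 ± 0.31), Ifit1 (1.91 ± 0.24), Gbp2 (1.79 ± 0.30) and the antigen peptide transporter Tap1 (1.07 ± 0.09, adjusted p = 1.6e-05) were among them. Of 26 NF-kB pathway members and feedback inhibitors, 13 rose (20 adjusted over the list alone), including the NF-kB inhibitor Nfkbia (1.46 ± 0.14, adjusted p = 7.1e-05), the phosphatase Dusp1 (1.29), Relb (1.25) and Birc3 (1.08). Of 22 immediate early genes 11 rose (19 adjusted over the list alone), among them Myc (1.53), Junb (1.52), Ier3 (1.51) and Fos (1.40 ± 0.14, adjusted p = 0.00012). Of 15 SOCS and STAT3 response genes 5 rose (9 adjusted over the list alone), led by the cytokine signalling suppressor Socs3 (1.82 ± 0.19, adjusted p = 0.00013), with Il1r1 (0.69) and Stat3 (0.57). These 4 lists were the ones that camera called both with its preset correlation (adjusted p = 1.23e-26, 9.46e-21, 9.46e-21 and 1.43e-08 in the order given) and with an estimated correlation (adjusted p = 0.0173, 0.0108, 0.0108 and 0.0108).

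Among 30 chemokines 8 rose (10 adjusted over the list alone), Cxcl3 among them (adjusted p = 0.0087). Camera gave the chemokines an adjusted p of 1.9e-07, and an adjusted p of 0.106 with an estimated correlation. The chemokine mean per array was uneven in WT LPS, at 0.821, 0.645, 0.097 and 0.05 in replicate order, against -0.584 to -0.257 in WT PBS. Among 21 pro-inflammatory cytokines 4 rose (8 adjusted over the list alone): Il1b (1.95 ± 0.35), Il1a (1.59 ± 0.30), Tnf (1.23 ± 0.30) and Csf1 (0.84 ± 0.18). That list had an adjusted p of 5.36e-05, and an adjusted p of 0.0714 with an estimated correlation. Of 20 neutrophil markers 3 rose (6 adjusted over the list alone), Ngp (1.94 ± 0.27), Clec4e (1.89 ± 0.40) and the formyl peptide receptor Fpr2 (adjusted p = 0.031), with a list adjusted p of 0.000551 and an adjusted p of 0.242 with an estimated correlation. Il1b and the caspase Casp4 (1.27 ± 0.24) were the members that rose of 12 inflammasome and pyroptosis genes (2 adjusted over the list alone; list adjusted p = 0.0197, and adjusted p = 0.242 with an estimated correlation). Of 28 hypoxia-response and glycolysis genes Pfkfb3 (1.26 ± 0.17) and Egln1 (0.54 ± 0.11) rose and Pfkfb4 (-0.63 ± 0.12) fell (3 up and 1 down adjusted over the list alone; list adjusted p = 0.018, and adjusted p = 0.436 with an estimated correlation). In lists that camera did not call, Icam1 (1.76 ± 0.26) and Thbs1 (0.61) rose and Vwf (-0.49) fell among 21 adhesion and coagulation genes (7 up and 1 down adjusted over the list alone; list adjusted p = 0.0999), and Adamts4 (1.60 ± 0.16), Timp3 (0.78) and Adamts1 (0.76) rose among 24 matrix and protease genes (4 up and 5 down adjusted over the list alone; list adjusted p = 0.565).

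Lists on the lower side after LPS in WT rested on few genes past the threshold, and none of them kept its call with an estimated correlation. Of 20 decidual and uterine smooth muscle markers Cnn1 and Actg2 fell (2 adjusted over the list alone; median -0.31, list adjusted p = 0.00149, and adjusted p = 0.106 with an estimated correlation). The mean of the decidual list per array was -0.43 ± 0.29 (SD, n = 4) in WT LPS and -0.07 ± 0.28 in WT PBS. For genes of these tissues, the share of maternal tissue in the samples and an effect of LPS cannot be told apart. Of 17 endothelial and pericyte markers the VEGF receptor Kdr fell (-0.53 ± 0.13; 4 fell adjusted over the list alone; list adjusted p = 0.000376, and adjusted p = 0.184 with an estimated correlation). Fasn (-0.94 ± 0.17) fell among 21 fatty acid genes (5 fell adjusted over the list alone; list adjusted p = 0.00146, and adjusted p = 0.156 with an estimated correlation). Mest (-0.49 ± 0.11) fell among 19 imprinted growth genes (1 fell adjusted over the list alone; list adjusted p = 0.00871, and adjusted p = 0.335 with an estimated correlation). None of 20 yolk sac endoderm and hepatocyte markers passed in limma (none adjusted over the list alone, and 1 up and 1 down at an unadjusted p under 0.05). Their median was -0.71 (list adjusted p = 0.000722, and adjusted p = 0.586 with an estimated correlation), and their means per array ranged from -0.97 to 1.41 within the WT PBS group. Among 41 Nrf2 target and antioxidant genes the transporter Abcc4 (0.49 ± 0.12) rose and Mgst1 (-1.01 ± 0.17) fell, with values of -0.34 ± 0.09 for Gclm (adjusted p = 0.055) and -0.68 ± 0.21 for Ephx1 (adjusted p = 0.11). That list (1 up and 4 down adjusted over the list alone) had a median of -0.09 and an adjusted p of 0.0378, and an adjusted p of 0.184 with an estimated correlation.

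WT PBS replicate 3 also carried raised liver-type transcripts: its mean over 24 acute-phase genes was 2.51 log2 units above the mean of all arrays, against -0.74 to 0.04 in the other WT PBS arrays. Leaving that array out gave 243 called genes for LPS in WT (170 higher and 73 lower), and 9 of the 10 largest falls (all but Pgc) no longer passed. Without it the Nrf2 target (adjusted p = 0.0699), inflammasome (0.069) and hypoxia (0.154) lists were no longer called, with medians of -0.083, 0.125 and 0.056. A call lost with fewer arrays does not by itself show that the shift came from the array left out. Without WT LPS replicate 3 the yolk sac and hepatocyte list was not called (0.0677), while camera gained the nutrient transporter (0.00534) and cell cycle (0.029) lists as lower and the prolactin (0.0121), spongiotrophoblast (0.0254), NK and T cell (0.0421) and adhesion (0.0479) lists as higher. Leaving out WT PBS replicate 1 gave 217 genes, WT PBS replicate 4 gave 267 and WT LPS replicate 1 gave 294, and a fit to the 8 WT arrays alone gave 139.

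**Figure D2:**
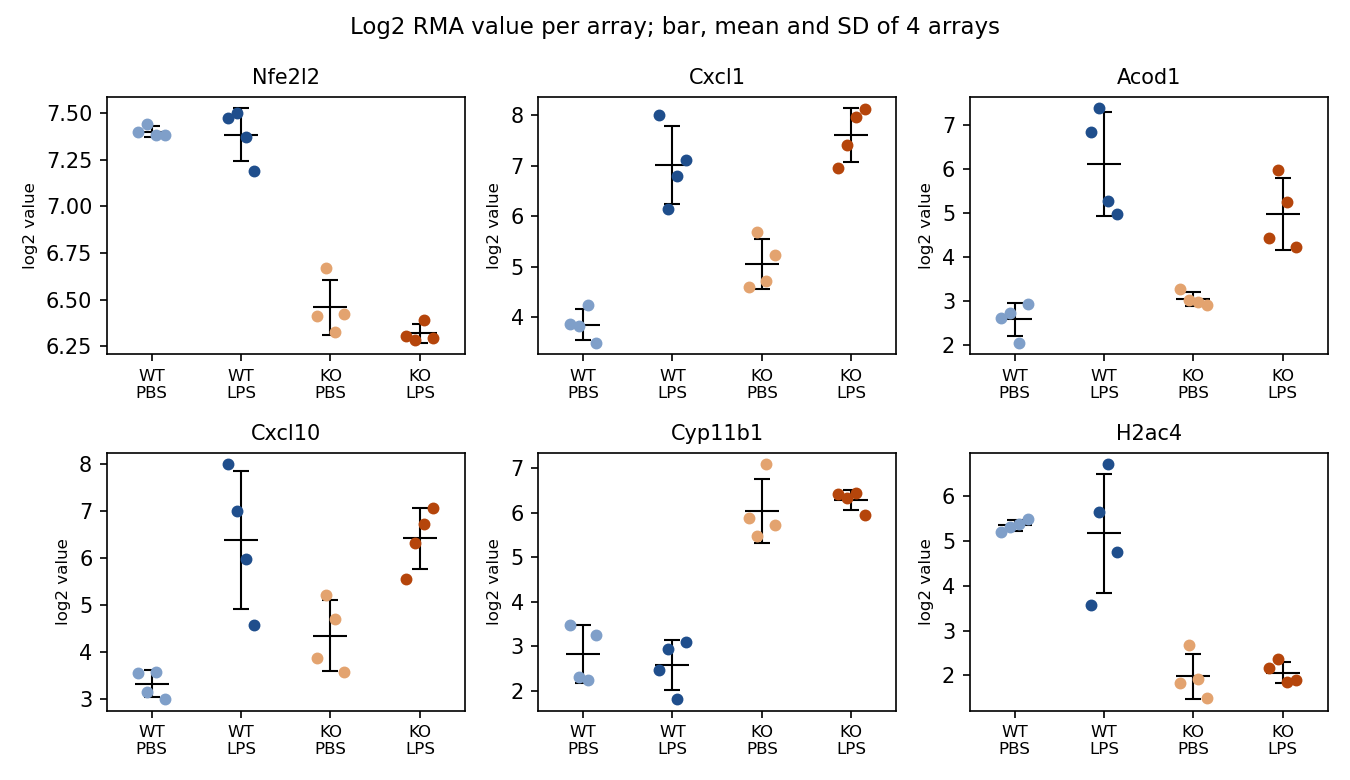
Log2 values of 6 genes on each array by group, with the mean and SD of 4 arrays as bars. Nfe2l2 lies near 7.40 in WT and near 6.46 or below in KO, Cxcl1, Acod1 and Cxcl10 are higher after LPS, and Cyp11b1 and H2ac4 differ between KO and WT under both treatments.

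In the KO placenta LPS also raised some chemokines and early response genes, while more genes fell than rose. Cxcl1 (2.56 ± 0.34, 5.89-fold, adjusted p = 0.0021), Cxcl2 (adjusted p = 0.0023), Madcam1 (2.09), Cxcl10 (2.07), the platelet and endothelial selectin Selp (1.97 ± 0.28), Acod1 (1.93 ± 0.46), Socs3 (1.76 ± 0.19, adjusted p = 0.00067) and Pcdha5 (adjusted p = 0.035) rose, and so did the embryonic globin chains Hbb-y (2.19 ± 0.57, adjusted p = 0.042) and Hba-x (1.60 ± 0.39). The falls were led by the cornified envelope gene Sprr1a (-2.57 ± 0.49, adjusted p = 0.013), Doxl1 (-1.99), Ly6g6c (-1.81), the lysosomal protease Ctss (-1.80), Cyp2s1 (-1.76), Fxyd6 (-1.72), Trank1 (-1.67), Elmod1 (-1.62), Scel (-1.59) and Mucl3 (-1.58 ± 0.17, adjusted p = 0.00067). Sprr1a was itself higher in KO than in WT under PBS, and both results use the same KO PBS arrays. In total 971 genes passed, 315 higher and 656 lower, 128 of them at least 2-fold, and 13% of genes had fully separated values (2.86% by chance).

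Inflammatory lists again lay on the higher side in KO. Of 22 immediate early genes 8 rose (13 up and 1 down adjusted over the list alone), including Myc (1.48), Ier2 (1.33), Junb (1.28) and Ier3 (1.15); of 26 NF-kB genes 7 rose (13 adjusted over the list alone), including Nfkbiz (1.12), Icam1 (1.09), Nfkbia (0.97) and Birc3 (0.56). Of 33 interferon-stimulated genes 5 rose (10 adjusted over the list alone), with Mx2 (1.23), Irf1 (0.78), Tap1 (0.72) and Ddx58 (0.66) the clearest. Il1b (1.52 ± 0.35), Tnf (1.24 ± 0.30), Il6 (adjusted p = 0.017) and Il23a (0.91 ± 0.17) were among the 5 of 21 cytokines that rose (8 up and 1 down adjusted over the list alone), and 5 of 30 chemokines rose (7 up and 1 down adjusted over the list alone), with Ccl4 (1.22) and Cxcl3 (adjusted p = 0.018) beside Cxcl1 and Cxcl2. Of 15 SOCS and STAT3 response genes 4 rose (5 adjusted over the list alone), with Socs2 (0.70) and Il1r1 (0.60) beside Socs3 and Junb. Camera gave these 6 lists adjusted p of 1.71e-07, 1.78e-07, 3.39e-05, 0.00124, 0.0251 and 0.00389 in that order, and an adjusted p of 0.183, 0.183, 0.414, 0.183, 0.523 and 0.183 with an estimated correlation.

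Other lists in KO concerned trophoblast, transport and macrophages. Of 22 nutrient transporters 4 fell (12 down and 2 up adjusted over the list alone), the amino acid transporters Slc7a5 (-1.29 ± 0.29), Slc1a5 (-0.88 ± 0.21) and Slc3a2 (-0.49 ± 0.10) and the imprinted Slc22a18 (-0.47 ± 0.12). Of 12 syncytiotrophoblast markers the gap junction gene Gjb2 (-0.95 ± 0.22) and Cebpa (-0.74 ± 0.14) fell (7 adjusted over the list alone). Of 23 monocyte and macrophage markers Ctss, the macrophage surface marker Adgre1 (-0.90 ± 0.20) and the MHC class II gene H2-Aa (adjusted p = 0.017) fell (10 adjusted over the list alone). The macrophage list mean was 0.332 in KO PBS and -0.15 in KO LPS, against -0.052 in WT PBS and -0.13 in WT LPS. The fall in KO thus started from a raised mean under PBS. Camera gave the transporter, syncytiotrophoblast and macrophage lists adjusted p of 4.28e-06, 4.96e-05 and 5.63e-07, and each an adjusted p of 0.183 with an estimated correlation. In KO LPS replicates 3 and 4 the syncytiotrophoblast mean was -0.62 and -0.59, against -0.01 and 0.05 in replicates 1 and 2. The transporter mean was likewise -0.39 and -0.35 there, against -0.09 and -0.04, and Slc7a5 read 7.84 and 8.10, against 9.04 and 9.26. Cpt1a (-0.44 ± 0.09) and Cpt2 (-0.41 ± 0.08), enzymes of mitochondrial fatty acid import, fell among 21 fatty acid genes (5 adjusted over the list alone; list adjusted p = 0.00227, and adjusted p = 0.183 with an estimated correlation). Pla2g4d (1.47 ± 0.21), Plac8 (0.74) and Ncam1 (0.70) rose among 14 spongiotrophoblast and glycogen cell markers (5 adjusted over the list alone; list adjusted p = 0.0134, and adjusted p = 0.523 with an estimated correlation). Mcm2 (0.41 ± 0.11) rose among 30 cell cycle genes (1 adjusted over the list alone; list adjusted p = 0.00297, and adjusted p = 0.523 with an estimated correlation). Hbb-y, Hba-x, Hbb-bh1 (adjusted p = 0.0037) and Car2 (0.57) rose among 18 erythroid markers and 1 fell (4 up and 1 down adjusted over the list alone; list adjusted p = 0.246). No yolk sac or hepatocyte marker of 20 passed in limma (none adjusted over the list alone, and 1 up and 3 down at an unadjusted p under 0.05). Their median was -0.90 (list adjusted p = 0.000881, and adjusted p = 0.527 with an estimated correlation). Pfkfb3 (1.21) and Pfkp (0.34) rose and Ndrg1 (-0.49) fell among 28 hypoxia and glycolysis genes (3 up and 4 down adjusted over the list alone; list adjusted p = 0.602).

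The count of 971 for LPS in KO was 178 without KO PBS replicate 1, 239 without KO LPS replicate 4, 289 without KO PBS replicate 4, 317 without KO LPS replicate 3 and 567 without KO PBS replicate 3. The calls of Hbb-y, Cxcl10 and Acod1 were each lost on leaving out 1 array for 6 of the 8 arrays compared, not the same 6 for each gene, and that of Cxcl1 was kept throughout.

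The calls of both genotypes were set side by side to see how alike the responses were. Of the genes called, 100 were higher after LPS in both genotypes, where independent lists would share 4.23 (two-sided Fisher exact p = 2.38e-112), and 41 were lower in both, against 5.38 (two-sided Fisher exact p = 1.44e-24). Only 3 genes were called in opposite directions. Because the Fisher tests take genes as independent units, their p-values do not measure the spread between arrays. Across genes, which are not independent replicates, the log2 fold changes of WT and KO correlated with Pearson's r = 0.433 (Spearman's rho = 0.373), with a slope of 0.448 for KO on WT. These comparisons share no arrays. The slope was fitted over all genes, most of them not called, with error in both fold changes. Error in the WT fold changes lowers the slope, so 0.448 does not show a weaker response in KO.

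**Figure D3:**
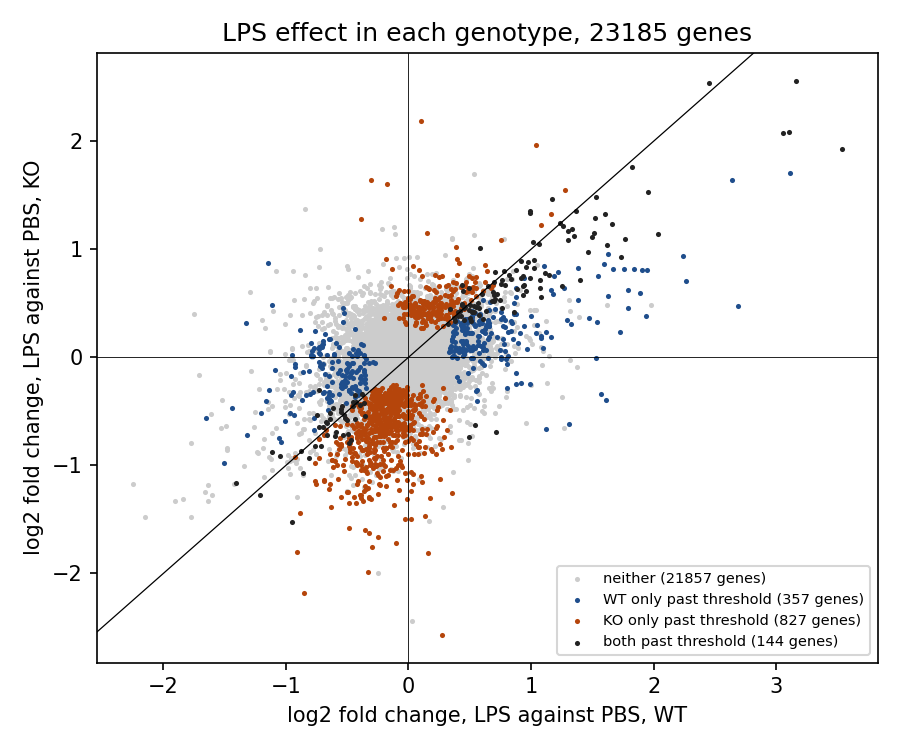
Log2 fold change after LPS in KO (vertical) against that in WT (horizontal) for 23185 genes, with the line of equal effects. Points are coloured by whether a gene passed in neither genotype (21857 genes), WT alone (357), KO alone (827) or both (144).

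The test of the difference itself, the interaction of genotype and LPS, called 2 genes. Pmvk, a kinase of the mevalonate pathway, rose after LPS by 0.99 ± 0.10 in WT (adjusted p = 0.00012), while its value in KO was -0.25 ± 0.10 (adjusted p = 0.16). The difference between these LPS effects was -1.24 ± 0.14 (adjusted p = 0.003). The class II histone deacetylase Hdac5 rose by 0.50 ± 0.11 in WT (adjusted p = 0.027) and fell by 0.73 ± 0.11 in KO (adjusted p = 0.0032). For Hdac5 the difference was -1.23 ± 0.15 (adjusted p = 0.0074). Both calls held with each array left out in turn. The next genes by p did not pass: Acpp (-1.41 ± 0.22, adjusted p = 0.081), Lncenc1 (-1.17 ± 0.19, adjusted p = 0.083) and Etnk1 (-0.96 ± 0.17, adjusted p = 0.12). At an unadjusted p under 0.05 there were 2039 of 23185 genes. In simulated data 25.4% of interaction effects of 1.5-fold were recovered, so real differences of that size could be missed. Apart from Pmvk, genes called in WT and not in KO, or the reverse, were therefore not shown to differ between genotypes in their LPS effect. The interaction of Ccl5 was -2.21 ± 0.68 (adjusted p = 0.34), that of Ltf -1.93 ± 0.71 (adjusted p = 0.45), that of Slc7a5 -0.96 ± 0.41 (adjusted p = 0.51) and that of Kdr 0.99 ± 0.18 (adjusted p = 0.12).

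Among the lists, interferon-stimulated genes had a smaller LPS effect in KO for 32 of 33 members (median difference -0.51, camera adjusted p = 1.95e-10), although no member passed in limma, alone or adjusted over the list alone (10 were lower at an unadjusted p under 0.05). With an estimated correlation the adjusted p was 0.383. The list mean per array after LPS was 0.82, 0.598, 0.529 and -0.057 in the WT replicates in order, and 0.032 to 0.422 in KO. WT LPS replicate 4 thus lay below every KO LPS array. Under PBS the interferon list mean was higher in KO (-0.203) than in WT (-0.475), which also lowers the LPS effect in KO. Members with the smallest p were Ifit1 (-1.10 ± 0.34), Mx1, Irf7 (-0.72 ± 0.22) and Ifit3 (-0.52 ± 0.16), with adjusted p of 0.34, 0.41, 0.34 and 0.34. Camera called 13 lists on this contrast, 4 towards KO and 9 towards WT, and none kept its call with an estimated correlation (lowest adjusted p = 0.383) or by fry. Without WT LPS replicate 3 the SOCS and STAT3 (adjusted p = 0.128), oxidative phosphorylation (0.0675) and nutrient transporter (0.0567) lists were no longer called. Without WT PBS replicate 3 the acute-phase list was called towards WT (adjusted p = 0.00334, median -0.51, against 0.87 with all arrays). Leaving out WT LPS replicate 4 gave 11 called genes, and leaving out WT PBS replicate 4 or KO LPS replicate 3 gave 4 each.

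The genotypes were then compared without LPS. Under PBS the KO placenta had higher Cyp11b1, the adrenal-type steroid 11-beta-hydroxylase (adjusted p = 0.00032), which had a mean of 6.04 ± 0.71 (SD, n = 4) in KO and array values of 2.23 to 3.49 in WT. BC018473 (adjusted p = 1.1e-06), Sprr1a (2.52), the protease inhibitor Spink2 (2.25), Klk14 (1.66), Npb (1.64), Ly6c1 (adjusted p = 0.04), Rgs4 (1.53), Gml (2.82-fold) and Ldlrad3 (2.56-fold) were also higher. Lower in KO were the histone genes H2ac4 (adjusted p = 0.0018) and H2bc4 (-1.94 ± 0.21), the placental cathepsin Ctsm (-3.21 ± 0.55, adjusted p = 0.0098), the H3K9 methyltransferase Suv39h2 (-2.48 ± 0.20, adjusted p = 7.8e-06), Myh4 (-1.76), Htr1d (-1.76), Norad (-1.75), Zfp970 (-1.64), Ccdc122 (adjusted p = 0.00068) and Ube2ql1 (-1.49). In total 184 genes passed, 64 higher and 120 lower in KO, 54 of them at least 2-fold, and 7.89% of genes had fully separated values (2.86% by chance).

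Of 41 Nrf2 target and antioxidant genes 1 was lower in KO under PBS, glutathione reductase Gsr (-0.64 ± 0.12, adjusted p = 0.02), also 1 adjusted over the list alone. It is named here after its value was seen. Wrn and Tex15, which lie within 1 Mb of Gsr, were called higher in KO under both treatments and are likewise named after their values were seen. The Nrf2 list had a median of -0.04 (camera adjusted p = 0.142). Of 22 immediate early genes Fosl1 (1.01 ± 0.19), Ier3 (0.86), Ccn1 (0.85) and Fos (0.78) were higher (9 adjusted over the list alone; list adjusted p = 2.23e-10, and adjusted p = 0.0789 with an estimated correlation). Tnip1 (0.53 ± 0.12) was the 1 NF-kB gene of 26 that was higher (5 adjusted over the list alone; list adjusted p = 2.39e-10, and adjusted p = 0.0789 with an estimated correlation). No heat shock gene of 14 passed in limma over all genes, 6 did adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. Hspa1a had a value of 1.76 ± 0.46 (adjusted p = 0.1) and Hspa1b of 1.30 ± 0.37 (adjusted p = 0.14). The heat shock list had an adjusted p of 2.51e-07, and an adjusted p of 0.0519 with an estimated correlation. The 19 oxidant producers and glutathione peroxidases had no member past the threshold, alone or adjusted over the list alone, and 4 higher and 1 lower at an unadjusted p under 0.05 (median 0.18, list adjusted p = 0.000314, and adjusted p = 0.0519 with an estimated correlation). Ly6c1 was the 1 monocyte and macrophage marker of 23 that was higher (5 adjusted over the list alone; list adjusted p = 2.84e-05, and adjusted p = 0.355 with an estimated correlation).

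The other lists that camera placed higher in KO under PBS had no member past the threshold over all genes in limma. They were the yolk sac and hepatocyte, NK and T cell, cell cycle and interferon-stimulated lists (list adjusted p = 0.000114, 0.000115, 1.21e-05 and 9.12e-05), with an adjusted p of 0.527, 0.355, 0.395 and 0.395 with an estimated correlation. In that order 0, 3, 4 and 1 members were higher adjusted over the list alone, and 5, 7, 6 and 8 at an unadjusted p under 0.05. Among the NK and T cell genes the granzymes Gzmd (3.03 ± 0.91, adjusted p = 0.17) and Gzmc (2.46 ± 0.85, adjusted p = 0.26) had large values and a wide spread. The inflammasome (list adjusted p = 0.0109), neutrophil (0.0216), SOCS and STAT3 (0.0303), erythroid (0.0304), apoptosis (0.0406), decidual (0.0499) and cytokine (0.0499) lists lay closer to the threshold. With an estimated correlation these 7 lists had an adjusted p of 0.355, 0.527, 0.373, 0.611, 0.443, 0.395 and 0.395. Adjusted over the list alone 1, 0, 1, 3, 0, 1 and 0 members were higher, and at an unadjusted p under 0.05 2, 3, 5, 6, 4, 5 and 1 were higher and 0, 0, 1, 2, 2, 3 and 0 lower. Among the decidual and erythroid genes 1 each was lower adjusted over the list alone. The 14 spongiotrophoblast and glycogen cell markers lay lower in KO, with none past the threshold over all genes, 5 adjusted over the list alone and 6 at an unadjusted p under 0.05 (list adjusted p = 0.000552, and adjusted p = 0.395 with an estimated correlation). Without WT PBS replicate 3 the count for KO against WT under PBS was 91, and the cytokine (adjusted p = 0.108), apoptosis (0.19), decidual (0.185) and neutrophil (0.0974) lists lost their calls. Camera then gained the acute-phase list as higher in KO (adjusted p = 0.000111, median 0.43, against 0.744 and the direction down with all arrays) and the unfolded protein response list as lower (0.00118, against 0.066). The acute-phase mean was uneven in KO PBS, at 0.906 in replicate 1 and -0.319 to -0.076 in the others. No list test left out a KO array. The count was 86 without KO PBS replicate 3, 89 without WT PBS replicate 4, 96 without KO PBS replicate 4, 114 without KO PBS replicate 2 and 118 without KO PBS replicate 1.

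After LPS more genes passed between the genotypes than under PBS. Higher in KO LPS were the WNT antagonist Sfrp4 (3.76 ± 1.05, adjusted p = 0.037), with a mean of 9.91 ± 0.10 in KO LPS and 6.15 ± 1.55 in WT LPS, and Cyp11b1 (adjusted p = 4.1e-05). The call of Sfrp4 was lost on leaving out WT LPS replicate 3, WT LPS replicate 4 or any 1 of the KO LPS arrays. Also higher were the protease inhibitor A2m (3.66), Rnase2a (3.65), Angptl7 (3.63 ± 0.44, adjusted p = 0.00029), Spink2 (3.32), Hbb-y (3.26), Ccn3 (3.23), Psca (3.10) and Scgb1a1 (adjusted p = 0.0021). Lower in KO LPS were the proton pump subunit gene Atp6v1g1 (adjusted p = 0.005), H2ac4 (adjusted p = 0.00081), Ly6g6c (-2.69), Ceacam-ps1 (-2.62), Ctsm (-2.56), Suv39h2 (-2.31 ± 0.20, adjusted p = 2.2e-05), Trank1 (-2.25), Htr1d (-2.09), the placental prolactin family gene Prl7c1 (-2.09) and Elmod1 (-2.06). In total 1960 genes passed, 923 higher and 1037 lower in KO, 356 of them at least 2-fold, and 12.7% of genes had fully separated values (2.86% by chance).

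By list, 14 of 30 cell cycle genes were higher in KO LPS (22 adjusted over the list alone), including Ccna2 (1.52 ± 0.24), the topoisomerase Top2a (1.20 ± 0.21), the kinase Cdk1 (1.04) and Plk1 (0.89). The cell cycle list had an adjusted p of 3.93e-12, and an adjusted p of 0.473 with an estimated correlation. Of 20 decidual and uterine smooth muscle markers 7 were higher (9 adjusted over the list alone), among them the progesterone receptor Pgr (1.94 ± 0.37) and the uterine homeobox genes Hoxa11 (1.89 ± 0.31) and Hoxa10 (1.85 ± 0.29), with Gja1 (1.33). The decidual list had an adjusted p of 0.000171, and an adjusted p of 0.192 with an estimated correlation. The mean of the decidual list per array was 0.26 ± 0.08 (SD, n = 4) in KO LPS and -0.43 ± 0.29 in WT LPS, where WT LPS replicate 3 had the lowest value of -0.84. Of 17 endothelial and pericyte markers 6 were higher (8 up and 2 down adjusted over the list alone), including Kdr (1.57 ± 0.13, adjusted p = 2e-05), Cldn5 (0.98), Tie1 (0.74) and Cdh5 (0.30), with a list adjusted p of 0.00706 and an adjusted p of 0.808 with an estimated correlation. Of 14 heat shock genes 4 were higher (7 adjusted over the list alone), Hsph1 (0.75), Hspb8 (0.66), Hspa8 (0.42) and Bag3 (0.41), with a list adjusted p of 0.00706 and an adjusted p of 0.473 with an estimated correlation.

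Of the 41 Nrf2 target and antioxidant genes, 5 were lower in KO LPS and 3 higher (6 and 3 adjusted over the list alone), and camera did not call the list (median -0.04, adjusted p = 0.787). Gsr (-0.52 ± 0.12), Osgin1 (-0.73 ± 0.15) and the transporter Abcc1 (-0.82 ± 0.16) were lower and thioredoxin Txn1 (0.53 ± 0.10) was higher. The remaining members that passed, named after their values were seen, were the glutamate-cysteine ligase subunit Gclc (-0.48) and sulfiredoxin Srxn1 (-0.60), both lower, and the pentose phosphate enzymes Taldo1 (0.34) and Tkt (0.43), both higher. Nqo1, a widely used Nrf2 target, differed by -0.38 ± 0.18 under PBS (adjusted p = 0.48) and by -0.21 ± 0.18 under LPS (adjusted p = 0.56), and is also named after its value was seen.

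Transport and trophoblast genes moved in both directions. Of 22 nutrient transporters 6 were lower and 2 higher (10 and 3 adjusted over the list alone), with Slc7a7 (-1.08 ± 0.20), Slc38a2 (-0.61) and Slc7a8 (-0.59) lower and the taurine transporter Slc6a6 (0.75) higher. Of 12 syncytiotrophoblast markers 3 were lower (4 adjusted over the list alone), among them Ovol1 (-1.21 ± 0.25), Gjb2 (-0.84) and Slco2a1 (-0.43). Both lists had an adjusted p of 0.0387, and an adjusted p of 0.851 and 0.845 with an estimated correlation. KO LPS replicates 1 and 2 had means within the WT LPS range for transporters (-0.093 and -0.042, range -0.099 to 0.133). The same held for syncytiotrophoblast markers (-0.011 and 0.046, range -0.108 to 0.288). Only KO LPS replicates 3 and 4 lay below these ranges, and no list test left out a KO array. Of 17 prolactin family genes Prl7c1, Prl5a1 (-1.60) and Prl3a1 (-1.14) were lower and 2 were higher, among them Prl6a1 (1.01), with 3 and 3 adjusted over the list alone. The prolactin list had a median of 0.04, a mean of -0.06 and an adjusted p of 0.966 in the direction up. Of 18 polyamine and nitric oxide genes 4 were lower, arginase Arg2 (-1.32 ± 0.20), Ddah2 (-0.94), the arginine transporter Slc7a1 (-0.67) and Gch1 (-0.51) (4 down and 1 up adjusted over the list alone; list adjusted p = 0.268). Hbb-y, Hba-x (adjusted p = 0.041) and Hbb-bh1 (adjusted p = 0.0051) were higher among 18 erythroid markers (3 up and 1 down adjusted over the list alone; list adjusted p = 0.115).

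Immune lists were compared in the same way. Of 33 interferon-stimulated genes Mx1 (adjusted p = 0.019) and Ifit3 (-0.69 ± 0.11) were lower in KO LPS (2 adjusted over the list alone; median -0.23, list adjusted p = 0.00663, and adjusted p = 0.845 with an estimated correlation). No neutrophil marker of 20 passed in limma (none adjusted over the list alone, and 3 lower at an unadjusted p under 0.05; median -0.18, list adjusted p = 0.0387, and adjusted p = 0.845 with an estimated correlation). The LPS receptor Tlr4 (1.41 ± 0.29), Tnfaip2 (0.71) and Tnip1 (0.47) were higher among 26 NF-kB genes (3 up and 2 down adjusted over the list alone; median -0.01, mean 0.05, list adjusted p = 0.787 in the direction up). Ly6c1 (adjusted p = 0.0018) and Ly6c2 (1.85) were higher and Lyve1 (-0.86) lower among 23 macrophage markers (2 up and 2 down adjusted over the list alone; list adjusted p = 0.495). Matrix and protease genes had 4 higher and 1 lower of 24 (5 and 1 adjusted over the list alone; list adjusted p = 0.0387, and adjusted p = 0.845 with an estimated correlation), with Timp2 (0.77) higher and Timp3 (-0.74 ± 0.12) lower. Oxidative phosphorylation genes had 3 higher of 29, Ndufa2 (0.40), Sdhb (0.35) and Cox4i1 (0.34) (4 adjusted over the list alone; list adjusted p = 0.0289, and adjusted p = 0.845 with an estimated correlation). The yolk sac and hepatocyte list had 1 higher of 20, Ctsz (0.40) (2 adjusted over the list alone; list adjusted p = 0.0186, and adjusted p = 0.864 with an estimated correlation).

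Without WT LPS replicate 3, the transporter (adjusted p = 0.201), syncytiotrophoblast (0.141), yolk sac (0.201), matrix (0.158) and oxidative phosphorylation (0.0705) lists lost their calls, and the decidual (3e-04), endothelial (0.000349) and cell cycle (1.21e-14) lists kept theirs. The erythroid list gained a call as higher in KO (0.00687, median 0.40). The number of calls, 1960, was 1067 without KO LPS replicate 4 and 1048 in a fit to the 8 LPS arrays alone.

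The genotype differences under the 2 treatments, which share no arrays, overlapped. Of the genes called, 46 were higher in KO under both PBS and LPS (2.55 for independent lists, two-sided Fisher exact p = 2.43e-50) and 88 were lower under both (5.37 for independent lists, two-sided Fisher exact p = 1.71e-92), with 0 called in opposite directions. Here too the Fisher p-values take genes as independent units. Across genes the log2 fold changes correlated with Pearson's r = 0.562 (Spearman's rho = 0.366), with a slope of 0.778 for LPS on PBS. Error in the PBS fold changes lowers this slope. Of the 1960 genes called under LPS, 1711 (87.3%) had the same sign under PBS. The interaction is also the genotype difference under LPS minus that under PBS, and it called 2 genes. Apart from those 2, genes called between genotypes only after LPS were not shown to differ more there than under PBS.

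A knockout allele brings along DNA from the line it was made in, so called genes near Nfe2l2 were counted, leaving out Nfe2l2 itself. Within 20 Mb of Nfe2l2, 5 of 479 genes were called under PBS and 178 of 22705 elsewhere (odds ratio 1.33, two-sided Fisher exact p = 0.433). After LPS 22 of the 479 genes were called and 1937 of 22705 elsewhere (odds ratio 0.516, two-sided Fisher exact p = 0.00151), a lower share near Nfe2l2; with a window of 5 Mb that odds ratio was 0.703 (p = 0.553).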

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

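Tests of liver RNA and yolk sac tissue in WT PBS replicate 3 and of neighbouring or co-inherited genes, and the permutation of residuals, were chosen after the result was seen, while the other splits of the arrays and the covariate tests were written before their results were seen.

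The LPS effect differed between genotypes, by the interaction test, for Pmvk (adjusted p = 0.00297) and Hdac5 (adjusted p = 0.00743). With the genotype and LPS main effects removed, the residuals of the 16 arrays were permuted, which takes the arrays as exchangeable. At least 2 genes were called in 3 of 100 draws (the real one among them), and the highest other called 5. Such a count was rare among the draws, but others passed it, so chance was not excluded. Permuting genotype within each treatment gave at least 2 genes in 7 of 100 draws, with 65 the highest other, which the rule written beforehand counts as chance. That permutation decides nothing, because it carries the genotype difference into the contrast. The draw with 65 kept 0 of the 4 KO arrays as KO under PBS and 3 under LPS, and none of the 39 other draws that kept equal numbers called a gene. Camera placed the LPS effect lower in KO for the interferon-stimulated (1.95e-10), NF-kB (3.32e-05), neutrophil (3.32e-05), macrophage (4.49e-05), immediate early (0.000548), syncytiotrophoblast (0.00148), nutrient transporter (0.00437), chemokine (0.0132) and SOCS and STAT3 (0.0239) lists, none of which kept its call with an estimated correlation (lowest adjusted p = 0.383) or by fry. For the NF-kB, immediate early and SOCS and STAT3 lists the mean after LPS was not lower in KO (0.31, 0.432 and 0.181) than in WT (0.261, 0.243 and 0.176). Under PBS their means were higher in KO (-0.107, -0.128 and -0.105) than in WT (-0.464, -0.546 and -0.251). The remaining lists had a lower mean in KO after LPS, and under PBS their means too were higher in KO. The macrophage mean after LPS was -0.15 in KO and -0.13 in WT, against 0.332 and -0.052 under PBS. That difference in LPS effect thus lay mostly in the PBS arrays. The interferon mean was 0.205 in KO and 0.473 in WT after LPS, against -0.203 and -0.475 under PBS. Camera placed the effect higher in KO for the cell cycle (3.32e-05), endothelial (0.000695), decidual (0.00148) and oxidative phosphorylation (0.0197) lists, and these 4 calls were lost in the same way. As many as 13 lists were called in 9 of 100 draws of residuals, with 16 the highest of the others, so chance was not excluded for that number of lists (4 draws and 17 with genotype permuted, which decides nothing here either).

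Of 192 groups of 4 arrays examined (9 genes and 39 list means in 4 groups), 9 held an array far from the other 3, where chance gives 9.6, so the number is no more than chance. In WT PBS replicate 3 Sfrp4 was 1.88 against 7.42 to 8.26 in the other 3 arrays (gap over range 0.869), the decidual mean was -0.48 against 0.01 to 0.11 (0.833) and the prolactin mean was -0.41 against 0.01 to 0.08 (0.858). The macrophage mean stood high in WT PBS replicate 2 (0.934) and in KO LPS replicate 2 (0.942), and the chemokine mean in KO PBS replicate 2 (0.837). The imprinted gene mean stood high in WT LPS replicate 3 (0.92), the Nrf2 target mean high in KO LPS replicate 1 (0.868) and the unfolded protein mean low in KO LPS replicate 2 (0.899).

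Rows without a gene name, which the comparisons did not use, also held differences. With all 25206 rows tested, 30 unnamed rows passed for LPS in WT, 49 for LPS in KO, 6 for KO against WT under PBS and 102 for KO against WT under LPS.

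WT PBS replicate 3 stood apart on the leading components. A list of 26 genes used mainly by adult hepatocytes, written without genes already seen to lead a component, had 22 measured members, and their median in this array was 1.16 log2 units above the median of the other WT PBS arrays; 22 of 22 were above it, and the highest of 10000 random lists matched on expression reached 0.206. The size 1.16 is uncertain, because members near it read under 2.50 in the other WT PBS arrays (Agxt at most 1.85, Hsd17b13 at most 2.29), not shown to lie above background. None of the 22 is in the 39 lists, G6pc, C9, Bhmt and Cyp8b1 were less than 0.2 above, and among the strongest were Cps1 (6.55 against at most 4.62 in the other 15 arrays), Cyp2e1 (6.09 against 4.48), Hpd (5.76 against 4.04) and Cyp2f2 (5.53 against 2.96). Visceral yolk sac tissue is argued against, since 6 visceral endoderm genes, 5 of them in the yolk sac list, had a median difference of 0.0862. An admixture of adult liver RNA is a candidate source of these transcripts, and no biological explanation was tested, because the labels give none for 1 array.

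The genotypes differed at 1960 genes after LPS. A difference in fetal sex between the pools is argued against, because arrays with a low Y-linked mean numbered 2 in WT LPS and 2 in KO LPS. With the mean of the Y-linked genes as a covariate, 96.1% of the 1960 genes stayed called with the same sign. That balance left the covariate little room to change this comparison. With the mean of the decidual list as a covariate, 3.79% of 1953 genes stayed called and 1879 kept their sign, while the median size of their differences went from 0.577 to 0.424 and the median SE from 0.129 to 0.207, so most calls ended through a smaller effect together with a wider error. The share of maternal decidua and uterine muscle in the samples and an effect of the genotype cannot be told apart here, because the decidual mean itself differs between these groups. The decidual mean was also lower in WT LPS (-0.43) than in WT PBS (-0.07). Tissue share may therefore enter the LPS effect in WT and the interaction too, where this covariate was not tried. Of 35 splits of the 8 LPS arrays only the real one called 1960 genes, and the highest other called 36. Chance is thus unlikely for the count, at 1 of 35 splits, the smallest share this test can give.

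The genotype differences shared by both treatments could mark chromosome segments that came with the knockout line. Of the 134 shared genes 42 had another of them within 1 Mb, against a median of 24 in 10000 random draws (95% between 12 and 36, permutation p = 0.003), including Gml, Cyp11b1 and Ly6c1, H2ac4 and H2bc4, and Gsr, Wrn and Tex15. Of 141 genes called after LPS in both genotypes 31 had such a neighbour. That number lay within its random draws (median 26, 95% between 15 and 39, permutation p = 0.2). The shares of 31.3% and 22% did not differ by the two-sided Fisher exact test (p = 0.101). Co-inherited segments and shared regulation of neighbours therefore cannot be told apart. A segment around Nfe2l2 is argued against as the source of most calls, since 178 of the calls under PBS lay outside it and 5 inside (odds ratio 1.33). The loss of Nrf2 itself stays open, as untested.

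For the other counts between 2 groups chance was unlikely as well. Of 35 splits only the real one reached 501 genes for LPS in WT (highest other 3), 971 for LPS in KO (highest other 1) and 184 for KO against WT under PBS (highest other 2). Each is a count of 1 split of 35, the smallest share these tests can give. A wrong split mixes the 2 real groups, so their difference widens the residual spread and lowers its count. The number of lists called by camera was less distinct. As many as the real 15 lists were called in 7 of 35 splits for LPS in WT (highest other 21), as many as 13 in 2 for LPS in KO (16), as many as 17 in 2 for KO against WT under PBS (17) and as many as 11 in 2 for KO against WT under LPS (14), so chance was not excluded for these numbers of lists.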

How the results depend on the processing

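The fetal sex covariate, the test of all rows and the list tests without 1 WT array were added after seeing the data. The 241 calls of named genes kept their direction under each alternative that could test them; the LPS effect on Nfe2l2 in WT, not called (-0.02), was 0.005 with array weights and ran from -0.056 without WT LPS replicate 2 to 0.048 without WT LPS replicate 4. Counts of called genes stayed within 1.5 times except as follows. Fitting only the 8 arrays compared gave 139 for LPS in WT and 1048 for KO against WT under LPS, with fewer samples to estimate the spread. Array weights gave 287 for KO against WT under PBS, and the cause was not tested. The replicate block gave 321 for LPS in WT, 565 for LPS in KO and 117 for KO against WT under PBS, and 1578 and 3 in the other comparisons; it changed no list call. Equal numbers do not pair the samples: the 24 same-numbered pairs correlated from -0.317 to 0.243 in their deviations from the group means, 2 of them above 0.1, and 1 of 16 arrays correlated best with its own number. Leaving out 1 array in turn gave 217 to 470 for LPS in WT, 178 to 1078 for LPS in KO, 86 to 180 for KO against WT under PBS, 1067 to 2089 for KO against WT under LPS and 2 to 11 for the interaction, with fewer samples in each; the lowest came without WT PBS replicate 1, KO PBS replicate 1, KO PBS replicate 3 and KO LPS replicate 4. Calls shared by the LPS responses numbered 27 at an adjusted p of 0.01 and 28 with at least 2-fold, against 141, because fewer genes pass. The lower share of calls near Nfe2l2 after LPS lost its call with a window of 5 Mb (odds ratio 0.703), which holds fewer genes. Of 241 named calls, 75 of 239 testable ones were lost with the 8 arrays, 45 with the block, 6 with the sex covariate, and 104 on leaving out at least 1 array. With the sex covariate camera lost the decidual list for KO against WT under PBS (adjusted p = 0.0528) and gained the spongiotrophoblast list for LPS in WT (0.0176) and the imprinted list for LPS in KO (0.0436), beside the prolactin and unfolded protein lists. Of 69 list calls 65 were lost with an estimated correlation and 40 by fry. Background level is unknown for these arrays, so what low signal limits was not measured.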

Other observations

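Fetal sex markers split the arrays. In 7 of 16 arrays the mean of the Y-linked genes Uty, Kdm5d and Eif2s3y lay between 1.74 and 2.26, and Xist, which is expressed from the inactive X of female cells, between 8.63 and 9.53. In the other 9 arrays the Y-linked mean lay between 4.68 and 5.66 and Xist between 5.60 and 7.24. The arrays with the low Y-linked mean numbered 2 in WT PBS, 1 in KO PBS, 2 in WT LPS and 2 in KO LPS. Several placentas of both sexes in 1 array would give a Y-linked signal, so these 7 arrays leave open how many placentas an array holds and whether the replicate is a pooled litter, which the labels do not settle.

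Visceral endoderm genes, chosen after the result was seen, varied between arrays of 1 group. The median of 6 such genes in WT PBS replicate 2 was 2.22 log2 units above that of the other WT PBS arrays, and in KO LPS replicate 1 it was 1.20 above its group. Lrp2 and Cubn are given here after their values were seen: Lrp2 reached 7.81 and Cubn 8.85 in WT PBS replicate 2.

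With all 16 arrays and no covariate, 12 of the 39 lists were not called by camera in any comparison. Those nearest the threshold were the prolactin family (lowest adjusted p = 0.0562), unfolded protein response (0.066), ribosomal proteins (0.0882), adhesion and coagulation (0.0999), polyamine and nitric oxide metabolism (0.13) and trophoblast giant cell markers (0.141). The acute-phase proteins (0.231), metal-binding stress genes (0.33), cholesterol biosynthesis (0.371), prostaglandin synthesis (0.472), B cell and mast cell markers (0.586) and fetal sex markers (0.776) lay farther from it. Of these 12, camera called 4 when WT PBS replicate 3 or WT LPS replicate 3 was left out or the sex covariate was added, and fry called the adhesion, ribosomal protein and giant cell lists for LPS in both genotypes. The acute-phase list, whose mean was raised in WT PBS replicate 3, was called without that array for KO against WT under PBS (0.000111, higher in KO) and for the interaction (0.00334, towards WT). Its mean was also high in KO PBS replicate 1 (0.906), which both of these calls include. The unfolded protein response was called lower in KO under PBS without that array (0.00118) and with the sex covariate (0.0179). The prolactin list was called higher after LPS in WT without WT LPS replicate 3 (0.0121) and with the sex covariate (0.0318), and in KO with the covariate (0.0436). The adhesion list was called higher after LPS in WT without WT LPS replicate 3 (0.0479).

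Other metabolic and stress genes differed between KO and WT under LPS in lists that camera did not call there. Among cholesterol genes, 5 of 20 passed for KO against WT under LPS (also 5 adjusted over the list alone), with Stard4 (1.15 ± 0.22), Dhcr7 (0.66 ± 0.13) and Nsdhl (0.34 ± 0.09) higher and Pmvk (adjusted p = 4.1e-05) lower in KO (list adjusted p = 0.495). The stress genes Sesn2 (-0.78 ± 0.12), Fas (-0.74 ± 0.19) and Bak1 (-0.34 ± 0.10) were lower and Apaf1 (0.46 ± 0.11) higher among 21 apoptosis genes (1 up and 3 down adjusted over the list alone; list adjusted p = 0.864). Among 28 hypoxia genes Adm (2.57-fold) was higher and Ndrg1 (-0.66 ± 0.12), Vegfa (-0.60 ± 0.15) and Hk1 (-0.41 ± 0.10) were lower (2 up and 4 down adjusted over the list alone; list median -0.02, mean 0.02, adjusted p = 0.722 in the direction down). Egr1 (1.16 ± 0.34) and Ccn1 (0.60 ± 0.14) were higher and Klf4 (-0.52 ± 0.11) and Klf2 (-0.58 ± 0.17) lower among 22 immediate early genes (6 up and 4 down adjusted over the list alone; list adjusted p = 0.182). Selp (1.39 ± 0.28) and Pecam1 (0.43 ± 0.12) were higher and Plaur (-0.58 ± 0.14) and Tfpi (-0.47 ± 0.08) lower among 21 adhesion genes (4 up and 3 down adjusted over the list alone; list median -0.06, mean 0.13, adjusted p = 0.964 in the direction up). The lipid carrier Fabp4 (1.70 ± 0.25) was higher among 21 fatty acid genes, and Cpt2 (-0.32) and Acadm (-0.28) were lower (1 up and 2 down adjusted over the list alone; list median 0.01, mean 0.02, adjusted p = 0.787 in the direction down).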
